A study of Mus musculus with 9 samples.

How the data were processed

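Gene expression was measured in left ventricles of male mice on 9 Affymetrix MoGene arrays, 1 array per sample. The labels put the arrays in 3 groups of 3: wild type on a vitamin A sufficient diet, Lrat-/- on the sufficient diet and Lrat-/- on a deficient diet. No wild-type mice on the deficient diet are among the samples, so an interaction of genotype and diet could not be tested. Lrat encodes lecithin retinol acyltransferase, which turns retinol into the esters in which vitamin A is stored.

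The array values used are log2 signals that the authors deposited per sample after RMA, which corrects for background, quantile-normalizes the arrays and summarises the probes of each probe set. The log2 scale is not written in the table and was read from the values, which have like quartiles on all arrays. Among probe sets over 2-fold, their group differences also scale with the log2 of the deposited ratios, with slopes of 0.915 to 1.05. Over all probe sets these correlate at 0.890 to 0.922, so the ratios were not computed from exactly these values. The submitters' processing notes also name R 3.1.2 and genome build mm8 without stating what each was used for, and state no filters. The authors deposited a comparison table that gives, per probe set, a ratio for each pair of groups, per the file headers. The same deposited table gives a p-value for each pair of groups, a p-value over the 3 groups, and a false discovery rate that equals the Benjamini-Hochberg adjustment of the 3-group p-value. How those ratios and p-values were computed is not stated.

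A further RMA table of the authors holds 9 value columns headed by scan codes that match no label. None of its values were used, and only its text columns were read, to name probe sets. The plan had named that table as the main source, so the per-sample values took its place, and the planned exchange of one table for the other was not run. The choice of groups, comparisons, tests, gene lists and the rule for naming genes was made before the data were examined.

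Of 35556 probe sets, 24785 were assigned to 1 gene each, which gave 22244 genes. The names came from the text columns of the 2 deposited tables that name probe sets, matched to a gene table of assembly GRCm38 by accession for 20853 probe sets, by symbol for 1780 and by the symbol of the comparison table for 1173, while 979 kept the name as written. Left out were 6612 control or unannotated design probe sets, 2434 with no gene named, 1723 for which the 2 tables name different genes, and 2 that name several. The gene table was used only for names and for which genes neighbour each other, since its assembly is not that of the files, and no coordinates are given. A gene measured by several probe sets was represented by the one with the highest mean over the 9 arrays.

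Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 9 arrays, contrasts, eBayes; two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 3 comparisons were Lrat-/- minus wild type on the sufficient diet, deficient minus sufficient diet within Lrat-/-, and Lrat-/- on the deficient diet minus wild type on the sufficient diet. A moderated F test asked for any difference among the 3 groups. Errors beside log2 changes are standard errors of that model with 3 arrays per group, and errors beside group means are standard deviations. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

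Of 43 lists of genes for heart function, metabolism, retinoid biology and cell types, 42 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated per list, and fry, were run beside it. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Correlations and covariances between comparisons that share the same arrays were set beside 100 simulations of groups without any difference. Overlaps of calls were counted but not simulated.

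Genes were named by a fixed rule. Lrat came first, on every array. Then came, among genes past the threshold whose groups do not overlap, the 10 with the largest rise and the 10 with the largest fall, or 5 in each direction for the comparison of genotype and diet together. Where fewer qualified, up to 5 per direction were filled from the lowest unadjusted p-values. Up to 4 members by lowest p-value were added for each list past the threshold or holding a gene past it, and any member of the 3 retinoid lists could be named. Predicted genes and clones without a functional symbol were counted and passed over. The replication-dependent histone genes of the closing section were chosen after their values were seen.

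Replicate numbers 1 to 3 recur in every group, and nothing in the labels says that they mark a shared litter or batch. The deviations of the arrays from their group means were therefore correlated across genes, which are not independent replicates. For the diet comparison all 3 pairs of same-numbered arrays correlated above 0.1, from 0.211 to 0.263, while pairs with different numbers lay between -0.141 and -0.0695, so the numbers were treated as pairing these arrays in an alternative fit with a replicate block. For genotype 0 of 3 pairs lay above 0.1, and for genotype and diet together 1 of 3.

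The alternatives were a fit of only the 2 groups compared, the replicate block, filters on dim genes at log2 6 and 7, eBayes with trend and robust, the mean of a gene's probe sets or each probe set alone, quantile normalization again, centring on the array median, arrayWeights, an adjusted p threshold of 0.10, a log2 minimum of 0.5, and leaving out each array in turn. Where an array is left out, its group is held by 2 arrays and the spread is shared with the other groups. A replicate block with only the 2 groups of the diet comparison, and the means of the erythroid or macrophage markers as covariates, were added after seeing the data.

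The pipeline was tested on simulated data for the genotype comparison, with 50 of 22244 genes changed at each of several sizes. It recovered 52% of genes changed by log2 0.5, 88% at 1, 100% at 2 and 100% at 4, with 12 unchanged genes called beside the 200 changed ones, and 0 of 40 unchanged lists passed. The simulated genes varied independently and the simulated lists were random. That result therefore does not show how often lists pass without a difference when their members vary together, as in most of the real lists. RMA values carry no detection calls, and the labels give no scan date or batch, so no batch could be tested. The number of arrays limits the precision.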

Results

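Left ventricles of male mice were profiled on 9 arrays, with 3 arrays in each of 3 groups: wild type on a vitamin A sufficient diet, Lrat-/- on the sufficient diet, and Lrat-/- on a deficient diet. The diets were given for 50 days and differed in retinol palmitate, which the sufficient diet held at 250000 U/kg. After RMA the array medians lay between 6.38 and 6.43 (log2). Across the 22244 genes tested, Pearson correlations were 0.991 to 0.996 within groups and 0.989 to 0.997 between groups, and 2 arrays of a group differed by a root mean square of 0.185 to 0.301. The 5222 negative control probe sets had a median of 4.54 and a 95th percentile of 7.53, against a median of 6.86 for the 22244 genes tested. On the first principal component (28.0% of the variance) wild-type arrays 1 and 2 stood apart at -27.5 and -17.3, while wild-type array 3, at 3.84, lay among the arrays labelled Lrat-/- (0.371 to 15.2). Wild-type array 3 stood apart on the second principal component (19.2% of the variance), at -22.3, where the other arrays lay between -6.38 and 17.8.

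The comparison of Lrat-/- with wild type on the sufficient diet asks what the knockout changes in the ventricle while vitamin A is supplied. Lrat itself, the enzyme that esterifies retinol for storage, had a log2 signal of 5.81, 5.78 and 5.73 on the 3 wild-type arrays, 7.29, 7.34 and 7.38 on the 3 arrays labelled Lrat-/- on the sufficient diet, and 6.84, 6.78 and 6.96 on the 3 labelled Lrat-/- on the deficient diet. The targeted gene was thus higher, not lower, where the labels give the knockout, by 1.57 ± 0.07 (SE) on the log2 scale (adjusted p = 1.49e-05), and the authors' deposited ratio for it was 2.72. All these signals lay below the 95th percentile of the negative controls. Where the probes of its probe set (10498978) lie relative to the deleted part of the gene is not given in the sources used here. All genotype directions that follow are those of the labels, which the Lrat signal calls into question without deciding whether they are wrong.

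On the arrays labelled Lrat-/- on the sufficient diet, 30 genes differed from wild type, 9 higher and 21 lower, and 15 of them by more than 2-fold. Gdpd3 and Hal differed most. Gdpd3, a glycerophosphodiester phosphodiesterase, averaged 12.11 ± 0.26 (SD, n = 3) in wild type and 6.32 ± 0.07 in hearts labelled Lrat-/-, a log2 change of -5.79 ± 0.15 (adjusted p = 1.87e-07). Hal, which takes the first step of histidine breakdown, changed by -3.82 ± 0.17 (adjusted p = 1.49e-05), from 9.75 ± 0.39 to 5.93 ± 0.15. Other enzyme genes that fell were the fatty acid elongase Elovl7 (-1.61 ± 0.17), the histamine methyltransferase Hnmt (-1.35 ± 0.13), the lysophospholipid acyltransferase Mboat2 (-1.27 ± 0.12) and Fah of tyrosine breakdown (-1.10 ± 0.15). The F-box gene Fbxo44 (-1.80 ± 0.21), the secretoglobin Scgb1c1 (-1.37 ± 0.20) and the zinc finger genes Rsl1 (-1.03 ± 0.12) and Zfp985 (-0.88 ± 0.12) also fell. Besides Lrat, the largest rises were in Pkig, an inhibitor of protein kinase A (1.55 ± 0.14, adjusted p = 0.00405), the interferon-inducible Ifi44l (1.22 ± 0.13), the R-spondin receptor Lgr6 (1.09 ± 0.06), the Ras-related Rerg (1.07 ± 0.11), the lectin-like Clec2e (0.83 ± 0.12) and Trim72, which takes part in membrane repair of muscle cells (0.65 ± 0.09). Of the 30 genes 18 had means under 7.53, the 95th percentile of the negative controls, in both groups labelled Lrat-/-, and 10 of these in wild type too. The sizes and ranks of their changes are thus uncertain. Among those named, Gdpd3, Hal, Elovl7, Hnmt, Fbxo44 and Rsl1 were this dim on both diets and Mboat2 on the sufficient diet. Lrat, Ifi44l, Rerg, Clec2e and Zfp985 were this dim in all 3 groups. All 30 had groups without overlap, as did 7.9% of all genes, where chance gives 10%. The authors' deposited ratios were 0.0299 for Gdpd3, 0.0744 for Hal, 0.348 for Elovl7, 0.412 for Hnmt and 2.48 for Pkig, and all 30 genes had the same direction in that table. Those ratios describe the same samples, so the like directions are no independent support. The authors' pairwise genotype p-values gave 2216 of 35556 probe sets under 0.05 and 13 after Benjamini-Hochberg adjustment.

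The number of genes past the threshold changed whichever array was left out, also with arrays outside the comparison. It was 100 without wild-type array 3, 14 without wild-type array 1 and 16 without wild-type array 2, 22, 11 and 11 without Lrat-/- sufficient arrays 1, 2 and 3, and 13, 13 and 14 without Lrat-/- deficient arrays 1, 2 and 3, which enter only through the shared spread. Lrat, Pkig, Lgr6, Gdpd3, Hal, Hnmt and Mboat2 passed without each of the 9 arrays. Ifi44l missed the threshold without Lrat-/- sufficient array 3 (adjusted p = 0.0512), Elovl7 without Lrat-/- sufficient array 2 (adjusted p = 0.0623), and Rerg without wild-type array 1 (adjusted p = 0.0552) or 2 (adjusted p = 0.0528). Rsl1 missed it without wild-type array 1 (adjusted p = 0.0704) or 2 (adjusted p = 0.0834) and Lrat-/- sufficient array 2 (adjusted p = 0.0744) or 3 (adjusted p = 0.0709). Trim72, Scgb1c1 and Fah passed without wild-type array 3 and missed the threshold without each of the other 8 arrays (adjusted p from 0.0679 to 0.156). Clec2e passed only without Lrat-/- deficient array 3 (adjusted p from 0.059 to 0.174 otherwise), Fbxo44 only without wild-type arrays 2 or 3 (adjusted p from 0.0527 to 0.141 otherwise), and Zfp985 only without wild-type array 3 or Lrat-/- sufficient array 1 (adjusted p from 0.0593 to 0.154 otherwise). With only the 2 groups compared in the model 7 genes passed. In that fit Pkig (adjusted p = 0.0806), Mboat2 and Rsl1 (both adjusted p = 0.0692), Clec2e (adjusted p = 0.0629), and Ifi44l and Elovl7 (both adjusted p = 0.0873) missed the threshold. So did Rerg, Trim72, Fbxo44, Scgb1c1, Fah and Zfp985 (adjusted p from 0.104 to 0.363). With the replicate block Clec2e (adjusted p = 0.108), Trim72 and Fbxo44 (both adjusted p = 0.0547) missed the threshold. Clec2e also missed it after quantile normalization again (adjusted p = 0.0524), and Zfp985 with the mean of its probe sets (adjusted p = 0.104).

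**Figure D1:**
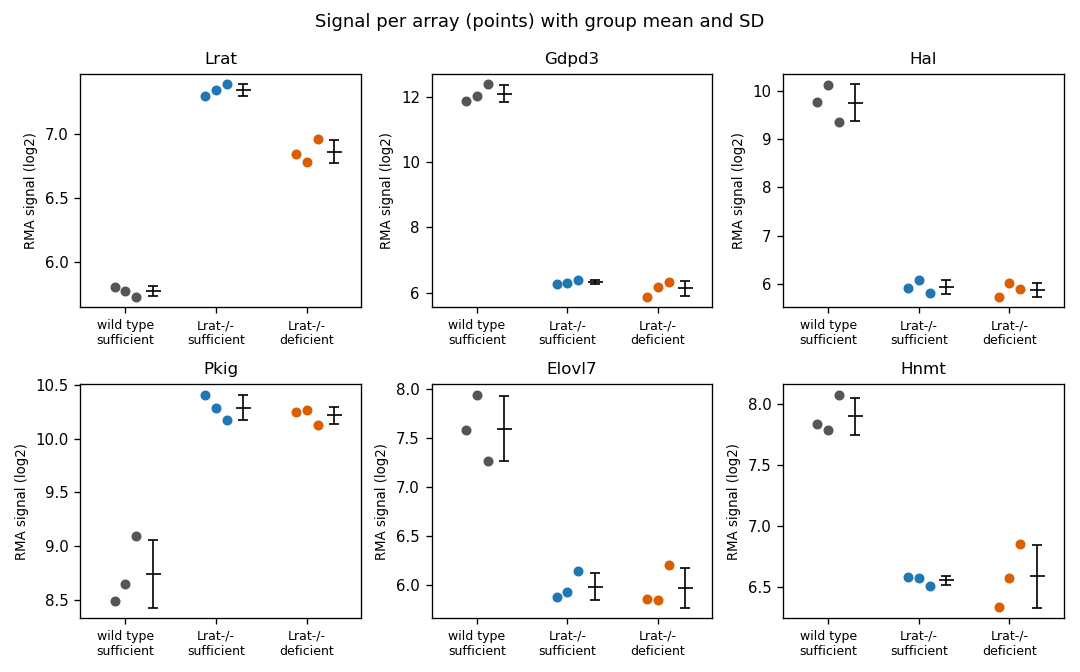
RMA signal (log2) of 6 genes on each of the 9 arrays, with 3 points per group and the group mean and SD beside them. Lrat is higher on the arrays labelled Lrat-/-, Gdpd3 and Hal fall from wild-type means of 12.11 and 9.75 to about the same low level on both diets, and Pkig is higher on both diets.

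Retinoid genes other than Lrat did not pass in the comparison on the sufficient diet. Of 31 measured genes of retinoid uptake, storage and metabolism, Lrat rose and 30 did not pass, and the list as a whole did not pass (camera, adjusted p = 0.804). The largest differences by p-value after Lrat were in Retsat (-0.41 ± 0.13, adjusted p = 0.524), the retinaldehyde dehydrogenase Aldh1a2 (-0.61 ± 0.19, adjusted p = 0.524) and Rbp2 (0.26 ± 0.08, adjusted p = 0.575). Among 20 genes induced by retinoic acid Lrat alone passed (list adjusted p = 0.180), with Rarb at 0.13 ± 0.08 (adjusted p = 0.795; 0.08 without wild-type array 2 and 0.20 without wild-type array 3). Of the 12 retinoid receptors and cofactors 0 passed (list adjusted p = 0.432).

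Of 42 gene lists 22 passed camera at the preset correlation, 2 higher and 20 lower, and with an estimated correlation 0 passed (lowest adjusted p = 0.621). By fry's directional test 0 passed (lowest adjusted p = 0.193), and by its mixed test 6. Without wild-type array 3, and without Lrat-/- sufficient array 3, 12 lists passed at the preset correlation. Among genes at log2 6 or more it was 11, and at 7 or more 13. Of 24 sarcomere genes 19 were lower. Adjusted over the list alone 3 fell, Actn2 (-0.31 ± 0.06), Myom2 (-0.42 ± 0.12) and Mybpc3 (-0.27 ± 0.08), 1 rose, Tcap (0.47 ± 0.13), and 0 passed over all genes (list adjusted p = 0.00166, and adjusted p = 0.621 with an estimated correlation). Of 29 interferon-response genes 22 were lower and 0 passed either way, with Irgm1 at -0.66 ± 0.18, Iigp1 at -1.13 ± 0.32 and Gbp3 at -0.64 ± 0.19. The interferon list passed with an adjusted p of 0.000136, and adjusted p = 0.622 with an estimated correlation, and was lost without wild-type array 1 (adjusted p = 0.16). Without wild-type array 3 these 3 genes passed over all genes (adjusted p = 0.0166, 0.0422 and 0.0193). Ifi44l, which rose, is not in the list.

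Extracellular matrix genes were lower in 32 of 38 cases, with 0 past either threshold. Their list had an adjusted p of 0.00166, and adjusted p = 0.621 with an estimated correlation, and was lost without wild-type array 1 (adjusted p = 0.104). Endothelial markers were lower in 18 of 19 cases (Vwf, -0.54 ± 0.18, and -0.34 without wild-type array 2), with a list adjusted p of 0.00524, lost without wild-type array 2 (adjusted p = 0.587) and Lrat-/- sufficient array 2 (adjusted p = 0.0688). Fibroblast markers were lower in 14 of 15 cases (Lum, -0.37 ± 0.11), with a list adjusted p of 0.00543, lost without wild-type array 2 (adjusted p = 0.0718). With an estimated correlation the endothelial list had adjusted p = 0.633 and the fibroblast list adjusted p = 0.621. Of 22 immediate early genes 20 were lower (Ccn1, -0.80 ± 0.25, and Nr4a1, -0.87 ± 0.42). Their list had an adjusted p of 0.00173, and adjusted p = 0.633 with an estimated correlation, and was lost without wild-type array 1 (adjusted p = 0.72). These values rested on that array, without which Ccn1 was at -0.49, Nr4a1 at -0.35 and the list mean at -0.03, against -0.31 with it. Of 27 genes of inflammatory cytokines and adhesion 21 were lower (Ccl3, -0.93 ± 0.24, and Cxcl9, -1.19 ± 0.38). That list had an adjusted p of 0.00842, and adjusted p = 0.621 with an estimated correlation, and was lost without wild-type arrays 1 (adjusted p = 0.123) and 2 (adjusted p = 0.243) and Lrat-/- sufficient arrays 2 (adjusted p = 0.0673) and 3 (adjusted p = 0.0889), and among genes at 6 or more (adjusted p = 0.0777). Without wild-type array 3 Cxcl9 passed over all genes (adjusted p = 0.0149).

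Cardiac ion channels and gap junctions were higher in 16 of 23 cases, and adjusted over the list alone 3 rose, among them Kcnj11 (0.49 ± 0.10) and Kcnh2 (0.38 ± 0.10), with 0 past the threshold over all genes. The list had an adjusted p of 0.00543, and adjusted p = 0.621 with an estimated correlation, and was lost without wild-type arrays 2 (adjusted p = 0.126) and 3 (adjusted p = 0.114). Without wild-type array 1 Kcnj11 passed over all genes (adjusted p = 0.0343). Cell cycle genes were lower in 25 of 32 cases (Bub1, -0.52 ± 0.14), while Mcm6, a subunit of the replicative helicase, rose adjusted over the list alone (0.85 ± 0.13; adjusted p = 0.0552 over all genes, adjusted p = 0.0145 without wild-type array 3, and from 0.0312 to 0.0479 in 6 other alternatives). Their list had an adjusted p of 0.00842, and adjusted p = 0.638 with an estimated correlation, and was lost without wild-type array 2 (adjusted p = 0.438) and Lrat-/- sufficient arrays 2 (adjusted p = 0.133) and 3 (adjusted p = 0.1), and among genes at 6 or more (adjusted p = 0.258) and at 7 or more (adjusted p = 0.998, with camera's direction turned). Erythroid and platelet markers were higher in 10 of 11 cases, on average by 0.42, with Ahsp at 1.33 ± 0.43. Their list had an adjusted p of 0.00173, and adjusted p = 0.621 with an estimated correlation, with 0 past either threshold. With the mean of these red cell markers as a covariate 4 genes passed the genotype comparison, and 8 of the 21 other lists kept their call. It took the mean change of the fibroblast list from -0.13 to -0.02 (adjusted p = 0.783), of the endothelial list from -0.18 to -0.07 (adjusted p = 0.354), of the ion channels from 0.11 to 0.04 (adjusted p = 0.287) and of the matrix list from -0.15 to -0.11 (adjusted p = 0.104). The cell cycle list kept a mean of -0.13 (adjusted p = 0.0654). Single arrays moved the endothelial, ion channel and matrix means as much. They moved the fibroblast mean less, to -0.10 without wild-type array 2 and -0.19 without wild-type array 3. The endothelial mean was -0.05 without wild-type array 2 and -0.34 without wild-type array 3, the ion channel mean 0.06 without wild-type array 2 and 0.21 without wild-type array 1, and the matrix mean -0.08 without wild-type array 1 and -0.23 without wild-type array 3. The remaining 12 lists were lower at adjusted p from 0.00524 to 0.0486, and each was lost without at least 1 array (adjusted p from 0.0508 to 0.967) and with an estimated correlation (adjusted p from 0.621 to 0.758). They are glycolysis, cholesterol synthesis, fatty acid synthesis, citric acid cycle, oxidative phosphorylation, heat shock, complement and coagulation, Y-linked genes with Xist, and markers of lymphocytes, white adipocytes, mesothelium and macrophages. Adjusted over the list alone 1 member fell in each of 4 of these lists, among them Procr (-0.80 ± 0.15), the protein C receptor.

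The comparison of the deficient with the sufficient diet within Lrat-/- asks what the loss of dietary vitamin A changes in hearts that lack the storage enzyme by their labels. Cell cycle genes were the clearest group. Of 32 measured, 29 were higher on the deficient diet and 14 rose adjusted over the list alone, among them Prc1 of the spindle midzone (0.92 ± 0.15), the ribonucleotide reductase subunit Rrm2 (0.44 ± 0.08) and the mitotic kinases Plk1 (0.63 ± 0.14) and Cdk1 (0.66 ± 0.16). These 4 genes, 12 of the 14 and 26 of the 32 had means under the 95th percentile of the negative controls in all 3 groups, so the sizes of their differences are uncertain. The mean of the list, set to 0 in wild type, was -0.12 ± 0.13 (SD, n = 3) on the sufficient and 0.23 ± 0.04 on the deficient diet, a difference of 0.36. The list had an adjusted p of 5.6e-19, and adjusted p = 0.468 with an estimated correlation, and passed at the preset correlation without each of the 9 arrays. Macrophage markers moved the same way (16 of 19 higher, on average by 0.18), and so did erythroid markers (10 of 11 higher, on average by 0.28). Both means rested on single arrays. The macrophage mean was 0.07 without Lrat-/- sufficient array 3 and 0.33 without Lrat-/- sufficient array 1, and the erythroid mean 0.11 without Lrat-/- deficient array 2.

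No single gene passed the threshold for diet with limma (0 of 22244, lowest adjusted p = 0.498), while 959 had an unadjusted p under 0.05, 495 higher and 464 lower. The authors' pairwise p-values gave 1740 probe sets under 0.05 and 0 after Benjamini-Hochberg adjustment. The lowest p-values among higher genes belonged to Prc1, the histone genes H2bc14 (0.66 ± 0.11), H3c1 (0.92 ± 0.16) and H3c4 (0.94 ± 0.17), and the transcription factor Tfec (0.48 ± 0.09). Among lower genes they belonged to Lrat (-0.48 ± 0.07, unadjusted p = 5.61e-05), the dynein heavy chain Dnah7b (-0.47 ± 0.08), the lymphatic and macrophage receptor Lyve1 (-0.66 ± 0.11), Tmem41b (-0.46 ± 0.09), each with an adjusted p of 0.498, and Casq2, the calcium store protein of the sarcoplasmic reticulum (-0.50 ± 0.10, adjusted p = 0.672). The groups of 9.5% of genes did not overlap, where chance gives 10%. With the replicate number as a block the count was 0, in the fit of 9 arrays and in the fit of these 2 groups. The pairing did move the unadjusted p-values. With the block 1051 genes lay under 0.05 in the fit of 9 arrays and 2008 in these 2 groups, against 1380 in these 2 groups without it.

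Ion channel genes went the other way on the deficient diet, with 21 of 23 lower. Adjusted over the list alone 2 fell, among them Kcnj11 (-0.38 ± 0.10), and 21 did not pass, such as Kcne1 (-0.42 ± 0.14, and -0.28 without Lrat-/- sufficient array 3). The list mean was 0.11 ± 0.01 (SD, n = 3) on the sufficient and -0.13 ± 0.04 on the deficient diet, and the list had an adjusted p of 1.08e-08, and adjusted p = 0.468 with an estimated correlation. Wild-type arrays 2 and 3, at -0.105 and -0.101, lay at the level of the deficient arrays (-0.162 to -0.088), and wild-type array 1 at 0.206. Between the deficient group and wild type the ion channel list did not pass (camera, adjusted p = 0.0726). All 12 retinoid receptors and cofactors were lower, with 0 past either threshold (Rarb, -0.23 ± 0.08, Rarg, -0.17 ± 0.08, and Rxra, -0.18 ± 0.10). Their list had an adjusted p of 0.00236, and adjusted p = 0.685 with an estimated correlation, and like the ion channels it passed at the preset correlation without each of the 9 arrays. Of 20 genes induced by retinoic acid 13 were lower and Lrat fell adjusted over the list alone, with Dhrs3 at -0.27 ± 0.11 (-0.17 without Lrat-/- sufficient array 1) and Stra6 at -0.20 ± 0.10 (-0.10 without Lrat-/- sufficient array 3). That list had an adjusted p of 0.0369, and adjusted p = 0.468 with an estimated correlation. It was lost without Lrat-/- sufficient arrays 1 (adjusted p = 0.231) and 2 (adjusted p = 0.0609) and Lrat-/- deficient arrays 1 (adjusted p = 0.113) and 3 (adjusted p = 0.0789), and with the replicate block in these 2 groups (adjusted p = 0.0536). The list of retinoid uptake, storage and metabolism did not pass (adjusted p = 0.845; its mean of 0.00 and its median of -0.00 differ in sign), with Bco2 at 0.36 ± 0.10 and Retsat at 0.29 ± 0.13.

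In all 15 lists passed for diet, 6 higher and 9 lower, and 0 with an estimated correlation (lowest adjusted p = 0.468) or by fry's directional test (lowest adjusted p = 0.402), with 5 by its mixed test. The number was 7 and 8 without Lrat-/- sufficient arrays 1 and 2, and 8 without Lrat-/- deficient array 3. Macrophage markers had an adjusted p of 0.00236, and adjusted p = 0.931 with an estimated correlation, with Ms4a7 at 0.88 ± 0.25, Lgals3 at 0.47 ± 0.14 and Cd68 at 0.36 ± 0.14, while Lyve1 fell adjusted over the list alone. They were lost without Lrat-/- sufficient arrays 2 (adjusted p = 0.107) and 3 (adjusted p = 0.348). White adipocyte markers were higher (adjusted p = 0.00236, and adjusted p = 0.592 with an estimated correlation; Adipoq, 1.01 ± 0.30, and Retn, 0.82 ± 0.29). They were lost without Lrat-/- deficient array 2 (adjusted p = 0.0514) and among genes at 7 or more (0.29 to 0.17, adjusted p = 0.292). Endothelial markers were lower in 17 of 19 cases (adjusted p = 0.00409, and adjusted p = 0.931 with an estimated correlation), with the water channel Aqp1 (-0.73 ± 0.18) past the threshold adjusted over the list alone. They were lost without Lrat-/- sufficient array 1 (adjusted p = 0.104) and with the erythroid marker mean as a covariate (-0.16 to -0.09, adjusted p = 0.166). Smooth muscle markers were lower in 12 of 15 cases (adjusted p = 0.0128, and adjusted p = 0.685 with an estimated correlation; Acta2, -1.27 ± 0.35). They were lost without Lrat-/- sufficient array 1 (adjusted p = 0.242) and Lrat-/- deficient arrays 1 (adjusted p = 0.0855) and 3 (adjusted p = 0.0768), and among genes at 7 or more (adjusted p = 0.0575). Calcium handling genes were lower in 16 of 22 cases (adjusted p = 0.0373, and adjusted p = 0.685 with an estimated correlation), with Casq2 past the threshold adjusted over the list alone and Atp2a2 at -0.18 ± 0.08. That list was lost without wild-type array 3 (adjusted p = 0.0549), Lrat-/- sufficient arrays 1 (adjusted p = 0.16) and 2 (adjusted p = 0.107) and Lrat-/- deficient arrays 2 (adjusted p = 0.124) and 3 (adjusted p = 0.247). It was also lost with the replicate block in these 2 groups (adjusted p = 0.0851) and with the erythroid covariate (-0.05 to -0.04, adjusted p = 0.155), with only the 2 groups in the model (adjusted p = 0.0598) and with arrayWeights (adjusted p = 0.0835).

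Beta-adrenergic and muscarinic signalling was lower in 18 of 26 cases (adjusted p = 0.0373, and adjusted p = 0.931 with an estimated correlation; Chrm2, -0.63 ± 0.23). It was lost without Lrat-/- sufficient array 1 (adjusted p = 0.398) and Lrat-/- deficient arrays 2 (adjusted p = 0.342) and 3 (adjusted p = 0.0807). Its call also ended with the erythroid covariate (adjusted p = 0.0778) and with arrayWeights (adjusted p = 0.081). Here and below, a call lost with a covariate does not by itself show that the mean change shrank. Interferon-response genes were higher in 23 of 29 cases (adjusted p = 0.0102, and adjusted p = 0.931 with an estimated correlation; Ifi27l2a, 0.80 ± 0.22). They were lost without Lrat-/- sufficient array 2 (adjusted p = 0.63) and Lrat-/- deficient array 3 (adjusted p = 0.0768). The mean change of the interferon list went from 0.14 to 0.05 with the erythroid covariate (adjusted p = 0.523) and to 0.12 with the macrophage covariate (adjusted p = 0.0592), which ended its call. Single arrays moved it as much, to 0.04 without Lrat-/- sufficient array 2 and 0.21 without Lrat-/- sufficient array 1. Oxidative phosphorylation genes were higher in 34 of 47 cases (adjusted p = 0.0102, and adjusted p = 0.931 with an estimated correlation), and were lost without Lrat-/- sufficient array 3 (adjusted p = 0.197) and Lrat-/- deficient array 2 (adjusted p = 0.107), and with the erythroid (adjusted p = 0.0501) or macrophage covariate (0.06 to 0.03, adjusted p = 0.424). Quantile normalization again moved this list most (0.06 to 0.02, adjusted p = 0.702). Erythroid markers (adjusted p = 0.0244, and adjusted p = 0.806 with an estimated correlation) were lost without Lrat-/- sufficient arrays 1 (adjusted p = 0.104) and 2 (adjusted p = 0.139) and Lrat-/- deficient array 2 (adjusted p = 0.551). The citric acid cycle (13 of 19 lower, adjusted p = 0.0373, and adjusted p = 0.931 with an estimated correlation) was lost without wild-type array 3 (adjusted p = 0.0549), Lrat-/- sufficient arrays 1 (adjusted p = 0.333) and 2 (adjusted p = 0.0529) and Lrat-/- deficient array 3 (adjusted p = 0.62), and with the replicate block in these 2 groups (adjusted p = 0.0536), only these groups in the model (adjusted p = 0.0505), genes at 7 or more (adjusted p = 0.0575) or arrayWeights (adjusted p = 0.0835). Fatty acid oxidation (28 of 34 lower, adjusted p = 0.0488, and adjusted p = 0.958 with an estimated correlation) was lost without wild-type array 3 (adjusted p = 0.0549), Lrat-/- sufficient arrays 1 (adjusted p = 0.398) and 2 (adjusted p = 0.118) and Lrat-/- deficient array 3 (adjusted p = 0.62). It was also lost under both dim filters, eBayes with trend and robust, and arrayWeights (adjusted p from 0.0508 to 0.081).

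**Figure D2:**
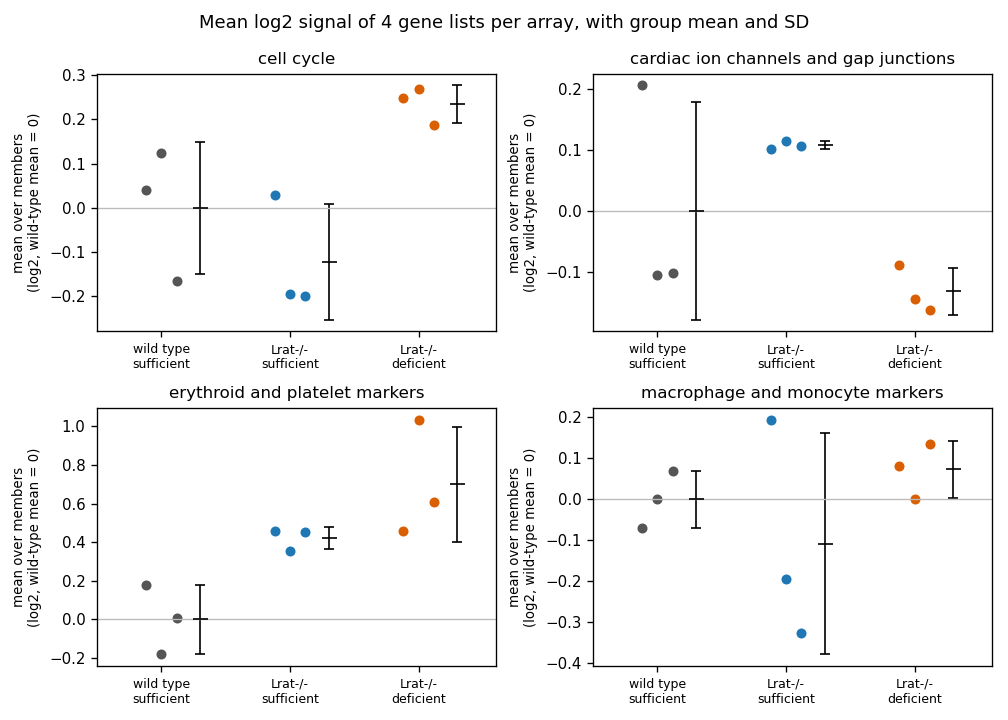
Mean log2 signal of the members of 4 gene lists on each of the 9 arrays, relative to the wild-type mean, with the group mean and SD. Cell cycle genes lie higher and ion channel genes lower on the 3 deficient arrays than on the 3 sufficient arrays labelled Lrat-/-, erythroid markers are highest on a deficient array, and the macrophage markers of these 2 groups overlap.

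The comparison of Lrat-/- on the deficient diet with wild type on the sufficient diet joins both factors. Here 29 genes differed, 13 higher and 16 lower. Gdpd3 (-5.98 ± 0.15, adjusted p = 1.39e-07), Hal (-3.88 ± 0.17, adjusted p = 1.95e-05), Elovl7 (-1.62 ± 0.17), Fbxo44 (-1.61 ± 0.21) and Hnmt (-1.31 ± 0.13) fell. Pkig (1.48 ± 0.14), Ifi44l (1.32 ± 0.13), Clec2e (1.10 ± 0.12), Lrat (1.09 ± 0.07, adjusted p = 0.000261, again higher where the labels give the knockout) and Mcm6 (1.06 ± 0.13, adjusted p = 0.0162) rose. Casq2 fell by 0.71 (SE 0.10, adjusted p = 0.0406), while its list of 22 calcium handling genes, 16 of them lower, did not pass (adjusted p = 0.0619). At an unadjusted p under 0.05 there were 2012 genes, and 11.5% of genes had groups without overlap, where chance gives 10%.

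This count also changed when single arrays of the comparison were left out. It was 270 without wild-type array 3, 15 without wild-type array 1, and 14, 12 and 11 without Lrat-/- deficient arrays 1, 2 and 3. Mcm6 missed the threshold without each Lrat-/- deficient array (adjusted p = 0.1, 0.0962 and 0.127), and Elovl7 without deficient arrays 1 (adjusted p = 0.05) and 2 (adjusted p = 0.0577). Fbxo44 passed only without wild-type arrays 2 or 3 or Lrat-/- sufficient array 2 (adjusted p from 0.0558 to 0.197 otherwise), and Casq2 only without wild-type array 3 or Lrat-/- sufficient array 3 (adjusted p from 0.0556 to 0.256 otherwise). With only the 2 groups compared in the model 7 genes passed, and Pkig, Clec2e, Elovl7, Hnmt, Mcm6, Fbxo44 and Casq2 missed the threshold (adjusted p from 0.0702 to 0.16). With the replicate block Mcm6 (adjusted p = 0.0599), Fbxo44 (adjusted p = 0.0835) and Casq2 (adjusted p = 0.0865) missed the threshold, and Casq2 also after quantile normalization again (adjusted p = 0.0908).

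Endothelial markers were lower in 19 of 19 cases, with Aqp1 (-0.81 ± 0.18) past the threshold adjusted over the list alone, and Esam (-0.47 ± 0.14) not (list adjusted p = 3.58e-07, and adjusted p = 0.599 with an estimated correlation). Cell cycle genes were higher in 25 of 32 cases. Mcm6 rose over all genes, and Nusap1 (0.86 ± 0.19), Prc1 (0.59 ± 0.15) and Birc5 (0.33 ± 0.09) adjusted over the list alone (list adjusted p = 6.81e-07, and adjusted p = 0.599 with an estimated correlation). All 4 were under the 95th percentile of the negative controls in every group, which leaves their sizes uncertain. Erythroid markers were higher on average by 0.70, and adjusted over the list alone 4 rose, among them Ahsp (2.20 ± 0.43), Slc4a1 (1.12 ± 0.34) and Alas2 (0.95 ± 0.29) (list adjusted p = 4.05e-06, and adjusted p = 0.599 with an estimated correlation). Without Lrat-/- deficient array 2 Slc4a1 was at 0.66 and Alas2 at 0.63. With their mean as a covariate 2 genes passed this comparison. The endothelial (adjusted p = 0.108), matrix (adjusted p = 0.145) and fibroblast lists (adjusted p = 0.97) were lost. Citric acid cycle genes were lower in 18 of 19 cases (Sdhb, -0.27 ± 0.08, and Sdha, -0.32 ± 0.11), and extracellular matrix genes in 34 of 38 (Sparc, -0.49 ± 0.11, and Mmp2, -0.67 ± 0.22), each with a list adjusted p of 2.42e-05, and adjusted p = 0.599 with an estimated correlation. Sarcomere genes were lower in 20 of 24 cases, and adjusted over the list alone 5 fell, among them Myh6 (-0.33 ± 0.08) and Myom2 (-0.52 ± 0.12), and 1 rose (list adjusted p = 0.00131, and adjusted p = 0.599 with an estimated correlation). Fibroblast markers were lower in 13 of 15 cases, with Lum (-0.45 ± 0.11) past the threshold adjusted over the list alone (list adjusted p = 0.00107, and adjusted p = 0.599 with an estimated correlation). These 7 lists passed at the preset correlation without each of the 9 arrays. Sarcomere genes were lost among genes at 7 or more (adjusted p = 0.0548). With arrayWeights Aqp1 (adjusted p = 0.0428) and Myom2 (adjusted p = 0.0472) passed over all genes. Without wild-type array 3 Aqp1 (adjusted p = 0.00637), Esam (adjusted p = 0.0382), Sparc (adjusted p = 0.0281), Mmp2 (adjusted p = 0.0415) and Myom2 (adjusted p = 0.0101) passed over all genes.

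In all 15 lists passed, 2 higher and 13 lower, 0 with an estimated correlation (lowest adjusted p = 0.599) and 0 by fry's directional test (lowest adjusted p = 0.283), with 11 by its mixed test. Without wild-type array 1 it was 9 lists, and among genes at 6 or more 9 and at 7 or more 6. Of the remaining 8 lists, all lower, lymphocyte markers (adjusted p = 0.0085) passed without each array. They were lost among genes at 6 or more (adjusted p = 0.0619) and 7 or more (adjusted p = 0.0739). Immediate early genes (adjusted p = 0.00383) were lost without wild-type array 1 (adjusted p = 0.794) and among genes at 7 or more (adjusted p = 0.127). Inflammatory cytokines, glycolysis, cholesterol synthesis, insulin and growth signalling, heat shock and fatty acid oxidation (adjusted p from 0.0085 to 0.0156) were each lost without at least 2 arrays (adjusted p from 0.0539 to 0.501). With an estimated correlation these 8 lists had adjusted p from 0.599 to 0.737. With the erythroid covariate the lymphocyte (adjusted p = 0.292), inflammatory (adjusted p = 0.0655), cholesterol (adjusted p = 0.276) and insulin lists (adjusted p = 0.905) were lost. A lost call does not by itself show that the mean change of a list shrank. Lrat was the member that passed over all genes in both lists of retinoid metabolism and retinoic acid induction, neither of which passed (adjusted p = 0.853 and 0.993). The retinoic acid list had a mean of 0.01, a median of -0.01 and a camera direction of lower. Adjusted over a list alone Dhrs3 (-0.43 ± 0.11) fell in both and Lpl (-0.47 ± 0.10) in the list of retinoid metabolism, while Rbp7 (1.11 ± 0.32, and 0.69 without wild-type array 3) and Tgm2 (-0.32 ± 0.13) did not pass. Without wild-type array 3 Lpl passed over all genes (adjusted p = 0.0378). Several lists that passed for diet did not pass against wild type (camera, adjusted p from 0.0523 to 0.899). They are ion channels, retinoid receptors, beta-adrenergic signalling, interferon response, oxidative phosphorylation, and smooth muscle, macrophage and white adipocyte markers. Their diet differences are thus not shown to be departures from wild type.

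Of the 39 genes that passed in at least 1 of them 20 passed in both, all 20 in the same direction. Both comparisons subtract the same 3 wild-type arrays, so shared calls of like direction arise in part by construction. All 30 genes of the sufficient diet had the same direction on the deficient diet. Their median absolute log2 change was 0.95 for genotype and 0.11 for diet, and 7 of the 30 had an unadjusted diet p under 0.05. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons with wild type correlated at 0.713, against 0.499 in groups simulated without any difference that share their controls. The covariance was 0.0229 against 0.00894. Part of this excess may come from the shared controls, since 3 wild-type arrays cannot be parted into sets of at least 2. Genotype and diet changes, which share the Lrat-/- sufficient arrays with opposite sign, correlated at -0.273, against -0.501 in simulation, with a covariance of -0.0064 against -0.0090. The simulation draws arrays independently, while same-numbered arrays of the 2 Lrat-/- groups deviated together, so both simulated correlations are too low for these arrays. The moderated F test over the 3 groups called 28 genes. That count was 97 without wild-type array 3, 10 and 15 without wild-type arrays 1 and 2, 15 without Lrat-/- sufficient array 2 or 3, 13, 12 and 11 without Lrat-/- deficient arrays 1, 2 and 3, and 17 with the replicate block. By the authors' deposited false discovery rate 10 probe sets lay under 0.05.

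**Figure D3:**
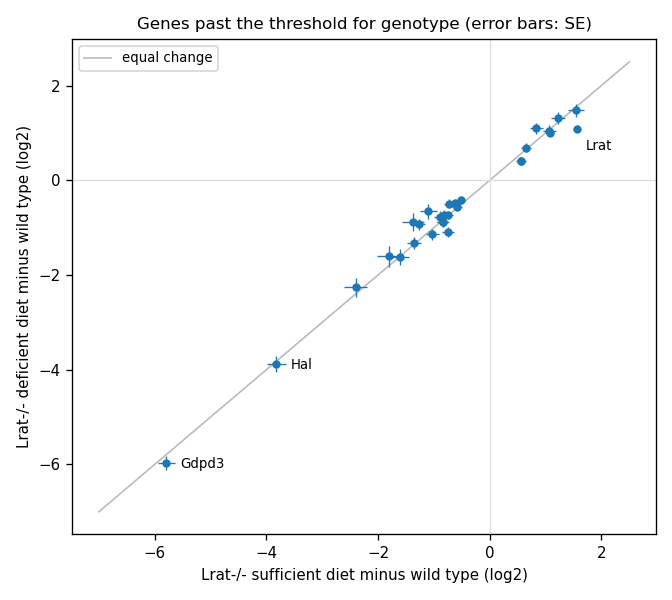
Log2 change against wild type of the 30 genes past the threshold on the sufficient diet (horizontal axis) and on the deficient diet (vertical axis) for arrays labelled Lrat-/-, with SE bars and a line of equal change. The points follow the line, with Gdpd3 at -5.79 and -5.98 and Hal at -3.82 and -3.88, and Lrat lies below it at 1.57 and 1.09. Both axes share the 3 wild-type arrays.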

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

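All results in this part are signals in probe sets outside the named genes, and all were looked for after the planned comparisons. Of 4159 probe sets not assigned to a single gene, 9 passed the threshold between arrays labelled Lrat-/- and wild type on the sufficient diet (8 higher and 1 lower), 0 between the diets and 9 with genotype and diet together, against 1, 0 and 0 of 6612 control and unannotated design probe sets.

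Transcripts of endogenous retroviruses were among them. A set of 4 probe sets with identical values, described as envelope mRNA of the Friend spleen focus-forming virus, was higher by 5.955 (log2) on the arrays labelled Lrat-/- on the sufficient diet, at 10.60 ± 0.09 (SD, n = 3) against 4.65 ± 0.26 in wild type. On the deficient diet it averaged 10.02 ± 0.12 (diet change -0.58 ± 0.13 (SE), adjusted p = 0.559). A gag protein mRNA clone was higher by 2.83 (log2), at 8.54 ± 0.32 against 5.71 ± 0.33. Of probe sets without any description, 10468877 was higher by 5.40 (9.78 ± 0.12 against 4.39 ± 0.68), 10389717 by 2.29 (8.37 ± 0.05 against 6.08 ± 0.20) and 10429968 by 1.81 (8.98 ± 0.16 against 7.17 ± 0.26). The wild-type means of all these probe sets lie under the 95th percentile of the negative controls, 7.53, so the sizes of the changes are uncertain. No explanation was tested for these signals, and like all genotype directions they follow labels that the Lrat signal calls into question.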

How the results depend on the processing

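A replicate block with only the 2 groups of the diet comparison and the erythroid or macrophage marker means as covariates were chosen after seeing the data, and the planned exchange of the deposited tables was not run because 9 value columns match no label. The block changed the diet count under neither fit (0 and 0), and diet stayed at 0 genes under every alternative and without each array. At an unadjusted p under 0.05, however, 959 genes differed by diet as reported, and 2008 with the block in the 2 groups alone. For genotype the count was 7 with only the 2 groups compared, 52 at an adjusted p under 0.10, 4 with the erythroid covariate, and 11 to 100 without 1 array (30 as reported, 21 with the block and 28 to 43 otherwise). For genotype and diet together it was 7 with only the 2 groups compared, 67 with arrayWeights, 2 with the erythroid covariate, and 11 to 270 without 1 array (29 as reported, 25 with the block and 27 to 39 otherwise). For the F test it was 17 with the block, 45 with arrayWeights, 44 at an adjusted p under 0.10, and 10 to 97 without 1 array. Fewer residual degrees of freedom explain part of the loss with 2 groups by construction, and otherwise the cause was not tested.

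The 22 lists of genotype were 17 after quantile normalization again and 16 with arrayWeights, and the 15 of diet 12 among genes at 7 or more and 11 with arrayWeights. Each named gene kept its direction under every alternative besides the marker covariates, for which this was not checked across the named genes. For genotype 494 gene values under the alternatives other than leaving out an array or adding a covariate kept their side of the threshold, 17 lost and 7 gained it. For genotype and diet together these were 345, 11 and 2, and for diet all 431 kept it. The list of genes induced by retinoic acid averaged -0.0872 to -0.0358 for diet without 1 array. Camera's direction turned in 5 genotype or combined lists, and their mean log2 changes were these. Cell cycle for genotype was -0.0359 among genes at 7 or more. Mesothelial markers for genotype lay between -0.506 (without wild-type array 3) and -0.00235 (without wild-type array 2), and at 0.0643 with the erythroid covariate. Oxidative phosphorylation for genotype lay between -0.0758 (without wild-type array 1) and 0.0107 (without wild-type array 3). Macrophage markers for genotype lay between -0.26 (without Lrat-/- sufficient array 1) and -0.000857 (without Lrat-/- sufficient array 3). Fibroblast markers for genotype and diet together were at -0.0064 with the erythroid covariate. The cause was not tested. Signals under the 95th percentile of the negative controls, 7.53, which include Lrat, and Gdpd3 and Hal on the arrays labelled Lrat-/-, cannot be told from background by their level alone.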

Other observations

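The histone genes, the neighbours of genes on other chromosomes than that of Lrat, the size of diet changes among genotype genes and the exchange of labels were tested only after the results were seen. The replication-dependent histone genes, whose messages are made in S phase, moved together on the deficient diet. Of 37 measured, 36 were higher than on the sufficient diet within Lrat-/-, 24 at an unadjusted p under 0.05 and 24 adjusted over the list alone, with 0 past the threshold over all genes. Their mean signal was 9.41 ± 0.17 (SD, n = 3) in wild type, 9.35 ± 0.10 on the sufficient and 9.81 ± 0.01 on the deficient diet in hearts labelled Lrat-/-. The mean difference between the diets was 0.46 (camera, p = 1.62e-37, and p = 0.00503 with an estimated correlation; fry, p = 0.00204). Against wild type the deficient diet group was higher by 0.40 (32 of 37 higher, p = 0.0202 with an estimated correlation), and the sufficient diet group lower by a log2 change of -0.06 (p = 0.592 with an estimated correlation). Members share much of their sequence, so a probe set of 1 histone gene can read several of them. The family was picked because 3 of its members had low p-values, so its p-values are no independent evidence of a difference.

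With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real genotype split gave 30 genes and the highest other 0, the diet split 0 and 0, and the split of genotype and diet together 29 and 0. For lists the numbers were 22 and 16, 15 and 16, and 15 and 17. The cell cycle mean differed by 0.36 between the diets and by at most 0.25 in the other splits, and the histone mean by 0.46 and at most 0.22. The histone genes were picked for low p-values in the real diet split, so their comparison with the other splits decides nothing. At an unadjusted p under 0.05 another split gave more genes than the real one in each comparison, 2191 against 1523 for genotype, 1388 against 959 for diet and 2296 against 2012 for both together. Of the other diet splits that part all 3 pairs of same-numbered arrays, as the real one does, the highest gave 7 lists, 523 genes at that p against 959, and a cell cycle difference of 0.21. For the F test over the 3 groups, 2 of 100 splits drawn from 280 gave at least the real count of 28, the real one included, a share under 0.05. The highest other gave 32 and keeps the wild-type arrays together, while splits that part them gave at most 3. The count thus reflects that the wild-type arrays stand apart from the others. It does not decide between a difference of genotype and a batch of these arrays, and says nothing on the diets. The splits also treat all arrays as exchangeable, although same-numbered arrays of the 2 Lrat-/- groups deviated together.

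Genes that differed between hearts labelled Lrat-/- and wild type lie mostly far from Lrat. Of 29 with a position besides Lrat itself 27 are on other chromosomes. DNA of another strain around the targeted locus would not hold these 27 genes, and whether such DNA acts on them from there was not tested. Within 20 Mb of Lrat lay 1 of 29 (3.45%, against 1.99% of all genes, Fisher's exact p = 0.4428, two-sided). That leaves DNA of another strain open for the genes nearby. Blood content was not decided. With the erythroid marker mean as a covariate the genes kept 100.6% of their change (median) and all 30 their direction. However, these genes were called for a small spread within groups, and the covariate is fitted on that spread. The marker mean itself parted the genotypes, at 0.178 or less in wild type and 0.355 or more on the other arrays. In that fit 4 calls were left as the median SE rose from 0.11 to 0.16. Of the 11 markers 4 lie above the 95th percentile of the negative controls, among them Hba-a2 at 14.25 in wild type and 14.37 on the sufficient diet, Alas2 at 10.94 and 11.45, and Pf4 at 10.91 and 11.15. Vitamin A from the diet stays open, since the median absolute diet change of 0.1116 in these genes decides nothing where 18 of the 30 lie under the 95th percentile of the negative controls in both Lrat-/- groups. Segments of another strain elsewhere in the genome are a candidate explanation, since 17 of the 27 had another such gene within 10 Mb, against a median of 6 and a 95th percentile of 11 in 10000 random sets (permutation p = 6e-04), though neighbouring gene families could give this too, and an effect of the genotype itself stays open.

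The Lrat signal was higher on the arrays labelled Lrat-/-. An exchange of 1 array of each genotype is argued against by 0 arrays on the wrong side of the gap. An exchange of the genotype labels of all arrays cannot be told apart from probes that still read a transcript of the targeted gene, because the gap of 0.9734 (log2) between the highest wild-type and the lowest Lrat-/- array is the value that raised the question. The strain difference named above may also contribute, and it was not tested on Lrat. If all genotype labels were exchanged, the genotype directions given here would turn and the diet comparison would be one within wild type.

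Cell cycle and histone genes were higher on the deficient diet. Blood content as the cause is argued against by differences of 0.3515 ± 0.13 (SE) for the cell cycle mean and 0.5245 ± 0.11 for the histone mean with the erythroid markers as a covariate, against 0.36 ± 0.10 and 0.46 ± 0.09 without. With the macrophage markers as a covariate they were 0.3016 ± 0.11 and 0.3919 ± 0.09, which argues against macrophage content as the whole cause. Of the 19 markers 17 lie above the 95th percentile of the negative controls, and 4 are in another list. Lyz2 was at 12.82 on the sufficient and 12.84 on the deficient diet, C1qb at 11.37 and 11.49, and C1qc at 11.11 and 11.32. These 3 moved little, but over all 19 markers 16 were higher on the deficient diet, on average by 0.18. Chance, dividing cells of another kind, a batch that follows the diet groups and an effect of the diet stay open, and which cells divide was not tested. The 10 splits are too few to decide on chance, and the cell cycle list did not pass camera with an estimated correlation (adjusted p = 0.468). Most of the cell cycle genes, 26 of 32, lie under the 95th percentile of the negative controls, as do 10 of the 37 histone genes. A rise in dividing cells on the deficient diet is thus a hypothesis from these arrays, and counts of nuclei in S phase by cell type on both diets would decide it.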
